A study of Mus musculus with 2 samples.

How the data were processed

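Polyadenylated RNA from the duodenum of adult mice of the C57BL/6J strain, 8 weeks old, was sequenced in 2 libraries, called replicate 1 and replicate 2 here after the biological replicate numbers in the labels. Per the labels, the tissue was pooled from male and female littermates, the RNA was depleted of ribosomal RNA, selected for poly(A) and for a length of over 200 nucleotides, and read as strand-specific pairs. Both libraries carry the same donor entry in the labels and different tissue-sample entries, so nothing in the labels says that the tissue came from separate animals. All p-values therefore compare these 2 libraries, and the spread between them may be technical in part.

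Each library had a deposited gene table and a deposited transcript table. Per the text files beside them, reads were aligned to mm10 and quantified against GENCODE M4 with spike-in sequences added. The aligner, the quantifier and their versions are not given in the sources used here. The deposited expected counts are fragments per gene or transcript, with fragments that map to several places shared out by the authors' quantifier, per the file headers, and they are not normalised. The deposited TPM values were scaled by the authors to transcript length and to the same total in each library, over all genes and spike-ins, per the file headers and the column sums. The deposited FPKM values were scaled by the authors to transcript length and to the number of fragments, per the file headers. The deposited isoform percent is the share of a transcript in the TPM of its gene, per the file headers. The deposited tables also hold posterior means of counts and TPM, which served as alternatives, and bounds on the TPM, which entered no test.

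A list of splice junctions and a list of contigs (transcribed stretches) were deposited for the series as a whole, in mm9 coordinates. Deposited counts of reads across each junction are not normalised, and they equal the sum of the counts named R1 and R2 in each entry. Which of R1 and R2 is which replicate is not given in the sources used here, so they were not assigned. The deposited score of a junction or contig lies lower where both libraries hold many reads, and what it is called was left as the authors gave it. The deposited signal of a contig is proportional to its read sum divided by its length. These coordinates were not set beside mm10 coordinates. Only intron lengths were compared with those of the annotation, which needs no position.

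Gene symbols, gene types, positions (mm10, 1-based), GC content and transcript lengths came from GENCODE M21 by the gene identifier without its version. A symbol was found for 42462 of the 43346 gene rows. Genes without a symbol held 0.0939% of the counts in replicate 1 and 0.0810% in replicate 2. Each gene table also had 26248 numbered rows, which were at 0 in both libraries, 96 rows of ERCC spike-ins and 1 row of phiX. All of these were left out of library sizes and tests. ERCC rows held 1.35% of the expected counts in replicate 1 and 1.36% in replicate 2.

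Depth was close, with 44977004 expected counts in replicate 1 and 45438504 in replicate 2, spike-ins and phiX included. Genes alone held 44272208 and 44710137, and the floor given next is relative to these gene totals. A count of 0 allows up to 3 counts, which is 0.0678 CPM (counts scaled to a common library total) in replicate 1 and 0.0671 in replicate 2. Folds against a library at 0 are therefore given as lower bounds, computed with 3 counts in that library. Folds against 1 to 3 counts are given with their interval. Intervals of folds are exact 95% Clopper-Pearson intervals of a gene's share of counts between the libraries. Intervals and floors cover counting error only, since the reads carry no molecular identifiers and the spread between animals is not in them.

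The design has 1 group, so no test between conditions was possible. Expected counts were rounded and scaled with TMM in edgeR 4.0.16 (R 4.3.3, limma 3.58.1), over genes with a mean count of at least 10. The common biological coefficient of variation came from edgeR with an intercept only. A chi-square test of homogeneity asked whether the libraries differ by more than sampling noise. Each gene was compared between the libraries with an exact two-sided binomial test given the TMM library sizes, adjusted by the Benjamini-Hochberg method. A gene is called higher in a library where the adjusted p is under 0.05 and the scaled ratio is at least 2-fold. Log2 ratios are replicate 2 over replicate 1 of TMM-scaled CPM plus 0.5, which understates the ratio of genes with few counts. Correlations were taken across genes of log2(TPM + 1), for genes with a TPM of at least 1 in either library. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.

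Before the data were examined, 41 gene lists were fixed for cell types, neighbouring organs and physiological states of the gut. Of their 452 different symbols, 448 were found. For each list with at least 3 members of a mean count of at least 10, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 50 bins. A median below the 2.5th or above the 97.5th percentile is called outside the random range, which describes these libraries and is not a p-value. For the goblet and mast cell lists, near these limits, 20 further draws were made after seeing the data. The levels of each list are sums of TPM, as mean ± SD over the 2 libraries.

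Genes were named by a rule fixed before the data were examined. It takes the 20 nuclear genes and the 3 mitochondrial genes of highest mean TPM, and the 4 members of highest mean TPM of each list (8 for neighbouring tissues), with exceptions to a list where a sentence needs them. It also takes the 12 genes with the largest ratio in each direction, among those with a mean count of at least 50 that passed the binomial test, and Xist, the 4 Y-linked genes and the main transcripts of the list genes. Members named outside that rule are marked as chosen after their values were seen. Some members that the rule takes are not reported here. Genes of near-identical families (defensins, trypsins, amylases, haemoglobins, the Reg family and immunoglobulin segments) share reads, so their single values are uncertain. The counting behind the tables is strand-specific only as far as the labels say that the libraries are.

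The coefficient of variation, the calls, the placing of lists and the correction for GC content and length were tested on simulated data. For 15921 genes, a simulated coefficient of 0.1, 0.3 and 0.6 was estimated as 0.101, 0.298 and 0.593. With counting noise alone, the call recovered 76% of the genes changed 3-fold, 84% of those changed 4-fold and 98% of those changed 8-fold, and called 0 of the unchanged genes. Genes changed 2-fold lie at the threshold and were not counted. With a simulated spread as large as the one estimated from these libraries, it recovered 54%, 72% and 92% of them and called 29.4% of the unchanged genes. A call therefore says that 2 libraries differ, not that tissues of 2 conditions do. The simulated share of 29.4% is higher than the 18.2% of genes called in the libraries themselves, so 1 common spread of that size is too wide for many genes. A planted list of 12 genes came out at the 100th percentile, and 5.5% of 200 random lists fell outside the range. In the correction of ratios for GC content and length (lowess with a span of 0.3), planted log2 changes of 2 in size were recovered as 2.11 and −1.91.

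Alternatives planned before the data were examined were DESeq2 1.42.0 size factors and dispersions, other filters on low counts or low TPM, another pseudocount, FPKM, posterior means, a 1.5-fold threshold, means in place of medians, and each library on its own. Scaling to the ERCC counts, and leaving out the pancreatic, gastric and Brunner's gland lists, were added after seeing the data. Junctions and contigs were also counted under stricter limits on score, reads and signal.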

Results

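Gene expression in the adult mouse duodenum, the first stretch of the small intestine, was measured in 2 libraries of polyadenylated RNA from animals 8 weeks old. The libraries are biological replicates of 1 group per the labels, so the data answer which genes the tissue expresses, at what level, and how far the replicates differ. Levels compared between genes carry a trend with GC content (Spearman's rho of 0.495 in replicate 1 and 0.499 in replicate 2), whose cause was not settled. Replicate 1 held 44977004 expected counts and replicate 2 held 45438504, spike-ins and phiX included. A TPM of at least 1 was reached by 12626 genes in replicate 1, by 11798 in replicate 2 and by 11340 in both. The ERCC spike-ins, synthetic RNAs added in known amounts, took 1.35% and 1.36% of the counts, and the 59 of 96 that were detected in both libraries had a Pearson correlation of 0.993 on the log2 TPM scale.

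By mean TPM the most abundant nuclear transcript was Fth1, which encodes the heavy chain of the iron store ferritin, at 39923 ± 41474 TPM (mean ± SD, n = 2, as for all levels given with an SD). It held that place in replicate 1, whereas in replicate 2, at 10597 TPM, it lay below Igha, Sprr2a2, Gm42418, Rn7sk, Apoa1 and Smim24. Sprr2a2, a small proline-rich protein of epithelia, followed at 17977 ± 3121 TPM, and Igha, the constant region of immunoglobulin A, at 16346 ± 881 TPM. The digestive protease precursor Ctrb1 had a mean of 15752 TPM with an SD of 22208, because it lay at 31455 TPM in replicate 1 and at 48.5 TPM in replicate 2. Other transcripts among the 20 most abundant were the small nuclear and cytoplasmic RNAs Rn7sk, Rn7s1 and Rn7s2, the ribosomal protein Rplp1 (9210 ± 4913 TPM), the trefoil peptide Tff3 (6653 ± 4546 TPM), the apolipoprotein Apoa1 (8076 ± 8157 TPM) and Actb (7604 ± 3864 TPM). Rn7s1 and Rn7s2 are near-identical copies with the same listed value, so their shared reads cannot be split. The remaining members of the 20 were Gm42418, Igkc, Smim24, Cox6a1, Cela2a, Atp5d, Atp5b, Clps and Ftl1. Mitochondrially encoded genes took 1.04% of TPM in replicate 1 and 1.02% in replicate 2, led by mt-Co1 (5397 ± 1222 TPM), mt-Co3 (2115 ± 1186 TPM) and mt-Atp6 (882 ± 72.5 TPM). The 10 most abundant genes held 21.6% of TPM in replicate 1 and 12.9% in replicate 2. The top 100 held 48.6% and 40.7%, and the top 1000 held 77.2% and 76.6%.

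Among the gene lists, those of the exocrine pancreas (55636 ± 69904 TPM) and of iron and calcium uptake (46569 ± 44156 TPM) had the highest mean sums, with SDs about as large as the means. Most of the iron and calcium sum came from the ferritin genes Fth1 (69250 TPM in replicate 1, 10597 in replicate 2) and Ftl1 (7193 and 4169). In replicate 2 alone the highest sums were those of enterocytes (37161 TPM), B and plasma cells (28126 TPM) and goblet cells (25078 TPM), above iron and calcium uptake (15346 TPM) and the exocrine pancreas (6206 TPM). Zg16, which the goblet list also holds, made up 4507 TPM of that exocrine pancreas sum, Clps 1083 TPM and Reg1 402 TPM. Genes of absorptive enterocytes summed to 26181 ± 15527 TPM, those of B and plasma cells to 25967 ± 3054 TPM, and those of goblet cells, which secrete mucus, to 17650 ± 10505 TPM. Paneth cell genes, which encode antimicrobial peptides of the crypt base, summed to 5390 ± 3820 TPM, with the defensins Defa3 and Defa24 in front. Enzymes and transporters for foreign compounds summed to 6249 ± 249 TPM. Hormone genes of enteroendocrine cells came to 1356 ± 513 TPM, with secretin (Sct, 515 ± 329 TPM), cholecystokinin (Cck, 332 ± 133 TPM), somatostatin (Sst, 214 ± 87.1 TPM) and Pyy (96.5 ± 11.4 TPM) highest. Stem cell genes summed to 274 ± 77.8 TPM, led by Olfm4 and Smoc2. Among other cell types, smooth muscle genes summed to 2318 ± 544 TPM, T lymphocyte genes to 545 ± 342 TPM, fibroblast genes to 561 ± 123 TPM, myeloid genes to 278 ± 104 TPM, tuft cell genes to 67.5 ± 20.7 TPM, endothelial genes to 59.6 ± 12.7 TPM, and neuron and glia genes to 47.2 ± 0.255 TPM. The ileal genes Fabp6 and Fgf15 had 0 counts in both libraries, which allows up to 0.0678 CPM in replicate 1 and 0.0671 in replicate 2.

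The libraries differed most in genes of organs that adjoin the duodenum. A pair of TPM values or counts is given for replicate 1 first, and the number in parentheses after a list's median is its percentile among matched random lists. Of the 33 exocrine pancreas genes, 30 were higher in replicate 1, 1 was higher in replicate 2 and 2 were not called. Ctrb1 (ENSMUSG00000031957.5, chromosome 8, 111686519 to 111691010, protein coding) was 596-fold higher in replicate 1 (95% interval 564 to 629). The elastase precursor Cela2a lay at 13097 TPM in replicate 1 and 27.2 TPM in replicate 2. Prss2, Try4 and Sycn were 459-fold, 673-fold and 320.2-fold higher in replicate 1. Clps, the cofactor of pancreatic lipase, was 10.2-fold higher and Reg1 was 22.3-fold higher, with 1083 and 402 TPM left in replicate 2. The member higher in replicate 2 was Zg16 (3.21-fold), which the goblet cell list also holds. Pnliprp2 (1.37-fold) and Bhlha15 (1.56-fold) did not pass the 2-fold limit.

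Stomach genes showed the same direction, with 10 of 12 higher in replicate 1, 0 higher in replicate 2 and 2 not called. The gastric peptide gene Gkn3 (ENSMUSG00000030048.4, chromosome 6, 87383256 to 87388935) lay at 6571 TPM in replicate 1 and 11.4 TPM in replicate 2, a 532-fold difference (95% interval 474 to 599.8). Tff1 was 198-fold higher in replicate 1, Gkn1 250-fold, Gkn2 285-fold, the mucin Muc5ac 323-fold, Ctse 106-fold and the pepsinogen Pgc 16.1-fold. Anxa10 had 960 counts in replicate 1 and 1 in replicate 2, a ratio of 823 with an interval of 147 to 32535. The subunits of the parietal cell proton pump were low in both, with Atp4a at 2.44 and 0.78 TPM and Atp4b at 0.15 and 0.41 TPM. Both genes of the Brunner's gland list, which mucous cells of the stomach express as well, were higher in replicate 1. Tff2 (ENSMUSG00000024028.7, chromosome 17, 31141049 to 31144282) was 415-fold higher (95% interval 375 to 461), at 10980 and 25.0 TPM, and the mucin Muc6 was 571-fold higher, at 1176 and 1.77 TPM.

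Pancreatic islet genes were mixed, with 3 of 6 higher in replicate 1. Ins2 lay at 522 TPM in replicate 1 and 1.03 TPM in replicate 2, and Ins1 had 2258 and 0 counts, at least 645-fold higher in replicate 1. The pancreatic polypeptide gene Ppy was at least 36.3-fold higher. Sst, Gcg and Iapp were not called, and intestinal endocrine cells express the first 2 of them. In the liver list 4 of 7 genes were higher in replicate 1, all at low levels, among them Ttr at 21.8 and 4.01 TPM and albumin (Alb) with 55 and 2 counts, a ratio of 23.6 with an interval of 6.22 to 199.5. The acinar, gastric and Brunner's gland lists together held 13.0% of TPM in replicate 1 and 0.630% in replicate 2. Without Zg16, the member that the goblet list also holds, the shares were 12.9% and 0.179%. The median log2 ratio, replicate 2 over replicate 1, was −7.05 for the acinar list and −5.89 for the stomach list (0th percentile of random lists for both), −1.59 for islets (0.01; −2.85 with genes at 0 set to their bound, −0.62 without the filter on low counts) and −1.28 for liver (0.07). The liver call ended when means replaced medians (−0.70).

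**Figure D1:**
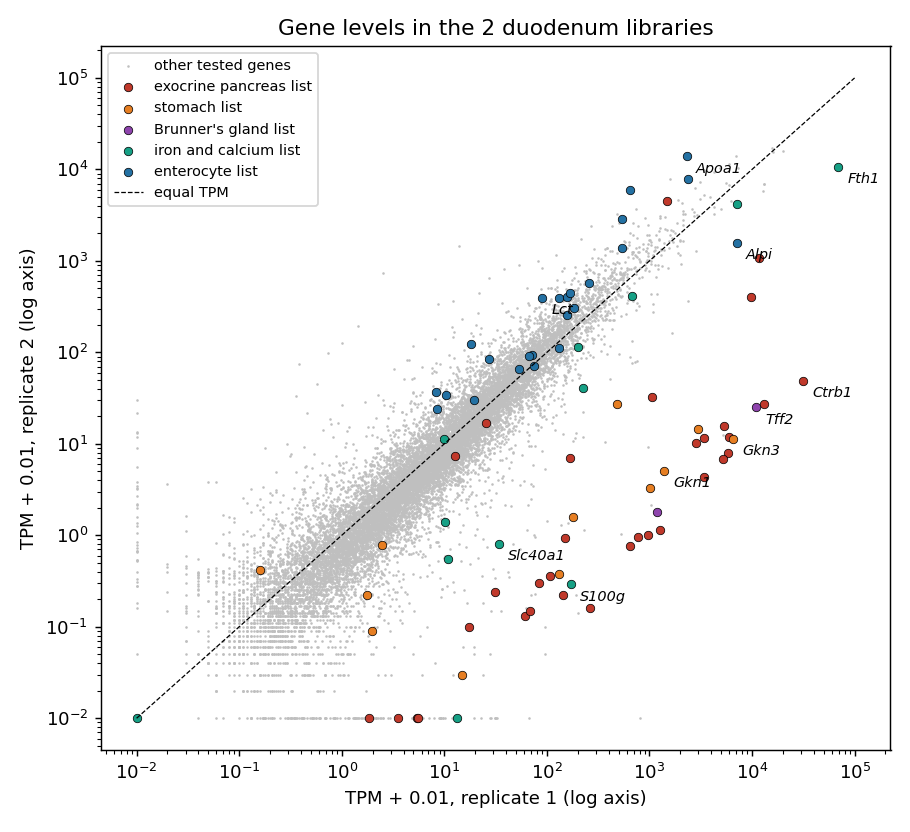
TPM of each tested gene in replicate 1 (x axis) and replicate 2 (y axis), both on log axes with 0.01 added, where each point is 1 gene and colours mark 5 gene lists. Most exocrine pancreas and stomach genes lie far below the line of equal TPM, such as Ctrb1 at 31455 and 48.5 TPM, and most enterocyte genes lie above it, such as Apoa1 at 2308 and 13844 TPM.

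Most genes of iron and calcium uptake were higher in replicate 1, while most other enterocyte genes were higher in replicate 2. Of 11 iron and calcium genes, 7 were higher in replicate 1, 0 in replicate 2 and 4 were not called. Fth1 (ENSMUSG00000024661.6, chromosome 19, 9980598 to 9985098) was 6.00-fold higher (95% interval 5.98 to 6.03), at 69250 and 10597 TPM. The other 6, named here after their values were seen, were the calcium-binding S100g, the calcium channel Trpv6, the calcium pump Atp2b1, the iron exporter Slc40a1, the iron importer Slc11a2 and the iron reductase Cybrd1. S100g had 2038 and 3 counts, a ratio of 582 with an interval of 199 to 2826, and Trpv6 had 1472 and 0 counts, at least 421-fold higher. Slc40a1 was 41.1-fold higher, Cybrd1 17.9-fold, Atp2b1 6.55-fold and Slc11a2 2.91-fold. Ftl1 (1.58-fold), the folate transporter Slc46a1 (1.47-fold) and Vdr (1.53-fold) did not pass the limit, and Heph had the opposite sign (1.29-fold higher in replicate 2, not called). The list median was −2.59, at the 0th percentile of random lists.

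Of 24 enterocyte genes, 15 were higher in replicate 2, 1 was higher in replicate 1 and 8 were not called. Apoa1 (ENSMUSG00000032083.8, chromosome 9, 46228580 to 46230466) was 6.61-fold higher in replicate 2 (95% interval 6.56 to 6.66). Its neighbours in lipid carriage Apoa4 and Apoc3 were 3.71-fold and 9.73-fold higher. The exception was the brush border phosphatase Alpi, 4.08-fold higher in replicate 1, at 7153 and 1568 TPM. In the list of lipid and sterol handling, 9 of 16 genes were higher in replicate 2, among them the triglyceride enzymes Dgat1 (3.28-fold), Mogat2 (2.24-fold) and Dgat2 (5.21-fold) and the cholesterol transporter Npc1l1 (5.63-fold). The lipoprotein receptor Scarb1 was the 1 member higher in replicate 1 (3.58-fold). The list medians were 1.60 for enterocytes (100th percentile) and 1.29 for lipids (99.99). Both differences stand beside the larger pancreatic and gastric share of replicate 1, and on the TPM scale the enterocyte median was 1.38 with those genes and 1.19 without them, the latter a choice made after seeing the data.

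Transcription factors of the proximal gut went both ways. The intestinal factors Cdx1 and Cdx2 were 2.81-fold and 3.01-fold higher in replicate 2, whereas Pdx1 (ENSMUSG00000029644.6, chromosome 5, 147269959 to 147275848), a factor of duodenum, pancreas and distal stomach, was 95.5-fold higher in replicate 1 (95% interval 74.5 to 124). Klf5 and Hnf4a were not called. In all, 4 of 12 were higher in replicate 2 and 2 in replicate 1, and the median of 0.39 lay inside the random range (40.7). It was 0.085 on the TPM scale, −0.11 on that scale without the pancreatic, gastric and Brunner's gland genes, and −0.079 as a mean. Of 4 genes of the distal intestine with enough counts, 3 were higher in replicate 2, including Guca2a (9.93-fold, 89.8 and 840 TPM). The water channel Aqp8 was higher in replicate 1 (24.8 and 2.24 TPM), and the median of 1.16 (99.8) fell inside the range as a mean (0.57), and was 0.47 without the filter on low counts, 0.72 on the TPM scale and 0.66 on that scale without the pancreatic, gastric and Brunner's gland genes. Genes for foreign compounds split into 8 higher in replicate 2, such as Cyp4f14 (3.35-fold) and Ces2e (2.36-fold), and 4 higher in replicate 1, with 12 not called, among them Gstm3 and Gstm1, and a median of 0.45 (83.0). The value was 0.046 as a mean, 0.21 under ERCC scaling and 0.097 on the TPM scale without the pancreatic, gastric and Brunner's gland genes, all inside the range.

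Most called genes of goblet and Paneth cells were higher in replicate 2. In the goblet list 5 of 9 genes were higher in replicate 2, among them Tff3 (2.98-fold), Spink4 (2.23-fold), Zg16 (3.21-fold) and Fcgbp (2.08-fold), and 2 were higher in replicate 1, which were Agr2 (2.98-fold) and Spdef (2.70-fold). In the Paneth list 6 of 11 were higher in replicate 2, such as Lyz1 (2.88-fold), Itln1 (3.73-fold) and Defa3 (5.07-fold), and 3 defensins were higher in replicate 1. The medians were 1.06 (97.6) and 1.17 (99.97). The goblet list lay at the limit, outside the range in 8 of 20 further draws of random lists, and both calls ended with means (0.46 and 0.48). Of 14 enteroendocrine genes 2 were higher in replicate 2 and 1 in replicate 1, with Sct at 2.73-fold and a median of 0.07 (66.3). Of 9 tuft cell genes 2 were higher in replicate 1 and 1 in replicate 2, while Ptgs1, Alox5ap and Trpm5 were not called, and the median was −0.52 (5.19), outside the range only on the TPM scale (−0.71). Of 8 stem cell genes only Sox9 was called, 3.12-fold higher in replicate 1, with a median of −0.36 (3.79). Cell cycle genes had 2 of 15 higher in replicate 1, both parts of the replicative helicase (Mcm2 and Mcm6, named after their values were seen), and a median of −0.52 (1.32) that lay inside the range with means (−0.46) and on the TPM scale (−0.56).

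Most genes of class II antigen presentation, of the interferon response and of T lymphocytes were higher in replicate 2. All 7 genes of class II antigen presentation were called, among them H2-Ab1 (ENSMUSG00000073421.5, chromosome 17, 34257689 to 34269419), 7.51-fold higher (95% interval 7.40 to 7.62), and Cd74, 5.56-fold higher, at 507 and 2581 TPM. H2-Aa and H2-Eb1 were 4.45-fold and 3.40-fold higher. Of 14 interferon-stimulated genes 10 were higher in replicate 2, with Irf7 at 5.55-fold, Isg15 at 8.52-fold and Oas1a at 4.04-fold. Of 12 T lymphocyte genes 7 were higher in replicate 2, such as Ccl5 (2.89-fold) and Cd3e (2.82-fold), and of 9 myeloid genes 4 were, among them the complement genes C1qa (2.34-fold) and C1qb (2.08-fold). The antimicrobial lectins Reg3b (5.68-fold), Reg3g (4.89-fold) and Reg3a (3.66-fold) were higher in replicate 2, and 4 of 8 genes of epithelial defence were called in that direction. The antibody transporter Pigr, at 1041 and 438 TPM, was not called. Medians were 2.22 for class II (100th percentile), 1.69 for interferon (100), 1.04 for T lymphocytes (100), 0.83 for myeloid cells (99.8) and 1.05 for epithelial defence (99.8), the last of which ended without the filter on low counts (0.27). On the TPM scale without the pancreatic, gastric and Brunner's gland genes they were smaller but still outside the range. In the same order they were 1.88, 1.26, 0.66, 0.49 and 0.64.

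Igha and Igkc were close in both libraries, at 1.18-fold and 1.32-fold, and 2 of 10 B and plasma cell genes were called, both higher in replicate 2, with a median of 0.42 (81.0). Mast cell genes had 1 of 4 called (Tpsb2, 3.17-fold higher in replicate 1) and a median of −0.94 (2.91), inside the random range but outside it under each alternative except DESeq2 size factors. Red blood cell genes were all 5 higher in replicate 2, with Hba-a2 at 5.85-fold, Hba-a1 at 3.15-fold and Hbb-bs at 3.53-fold, and a median of 1.81 (99.9).

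Several fat cell genes were higher in replicate 2, and the medians of smooth muscle and fibroblast genes lay towards replicate 1. Complement factor D (Cfd), which fat cells secrete, was 41.7-fold higher in replicate 2, at 8.75 and 334 TPM, and Plin1 and Adipoq were 29.9-fold and 15.8-fold higher. In that list, which also holds genes of the serosal lining, 5 of 9 were called and the median was 1.02 (99.98). Of 12 smooth muscle genes 3 were higher in replicate 1, among them Actg2 (2.18-fold), and Acta2 (1.19-fold) was not called, with a median of −0.36 (0.06). Of 11 fibroblast genes 2 were higher in replicate 1, including fibronectin (Fn1, 2.52-fold), and Fbln1 was higher in replicate 2 (2.81-fold), with a median of −0.49 (0.59). The TPM sum of the fibroblast list was higher in replicate 2 (475 and 648 TPM). The smooth muscle and fibroblast lists lay inside the range with means (−0.59 and −0.46). In the list of interstitial cells of Cajal, the pacemaker cells of gut muscle, Ano1 (5.73-fold) and Etv1 (5.50-fold) were higher in replicate 1 and Kit was not called, with a median of −1.86 (0.15). Neuron and glia genes had 2 of 13 higher in replicate 1 and 1, Vip (2.26-fold), higher in replicate 2, with a median of −0.53 (6.52). None of 9 endothelial genes was called, Vwf, Cdh5, Pecam1 and Flt4 among them, and the median was 0.00 (67.3). Of the skeletal muscle genes only Ckm (36.1 and 29.1 TPM) and Acta1 (9.58 and 14.0 TPM) had enough counts, and neither was called.

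Genes that follow feeding, time of day and handling also differed. Sterol synthesis genes leaned towards replicate 1, with 3 of 14 called, among them Insig1 (2.44-fold), and Dhcr7 and Fdps not called, and a median of −0.75 (0.01). Of 13 genes of fatty acid oxidation and ketogenesis 5 were higher in replicate 1, including Cpt1a (2.66-fold), and 2 in replicate 2, including Angptl4 (2.51-fold), with a median of −0.45 (0.81). Of 10 clock genes of the Per and Dbp phase 5 were higher in replicate 2, among them Nr1d1 (2.44-fold), Dbp (3.77-fold) and Nr1d2 (2.97-fold), with a median of 0.93 (99.96) that was 0.46 on the TPM scale and 0.28 on that scale without the pancreatic, gastric and Brunner's gland genes. The opposite phase had Nfil3 higher in replicate 1 (2.32-fold), Cry1 higher in replicate 2 (2.80-fold) and Arntl, Npas2 and Clock not called. Its median of −0.72 (1.93) lay inside the range with means (−0.18) and on the TPM scale (−0.82). Immediate early genes had 7 of 13 higher in replicate 2, with Fos at 4.35-fold, Zfp36 at 2.95-fold, Jun at 2.71-fold and Junb at 2.30-fold, and a median of 1.20 (100). Genes of heat shock and of the unfolded protein response went both ways, with Hspa5 2.18-fold higher in replicate 1 and Herpud1 2.30-fold higher in replicate 2, and a median of −0.13 (15.9). Of 4 nuclear noncoding RNAs Meg3 was higher in replicate 1 (2.45-fold), Neat1, Malat1 and Kcnq1ot1 were not called, and the median was −0.17 (15.5), which lay outside the range on the TPM scale (−0.70).

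Of the 41 lists 38 could be tested, and 26 lay outside the random range, 12 below it and 14 above it. For lists of independently drawn genes 1.9 would be expected. Genes of the same list can vary together, so that number is not a chance level for these lists. Of these 26, 17 stayed outside under each alternative tried. For all 41 lists the counts of called genes adjusted over the list alone equalled those adjusted over all genes tested.

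**Figure D2:**
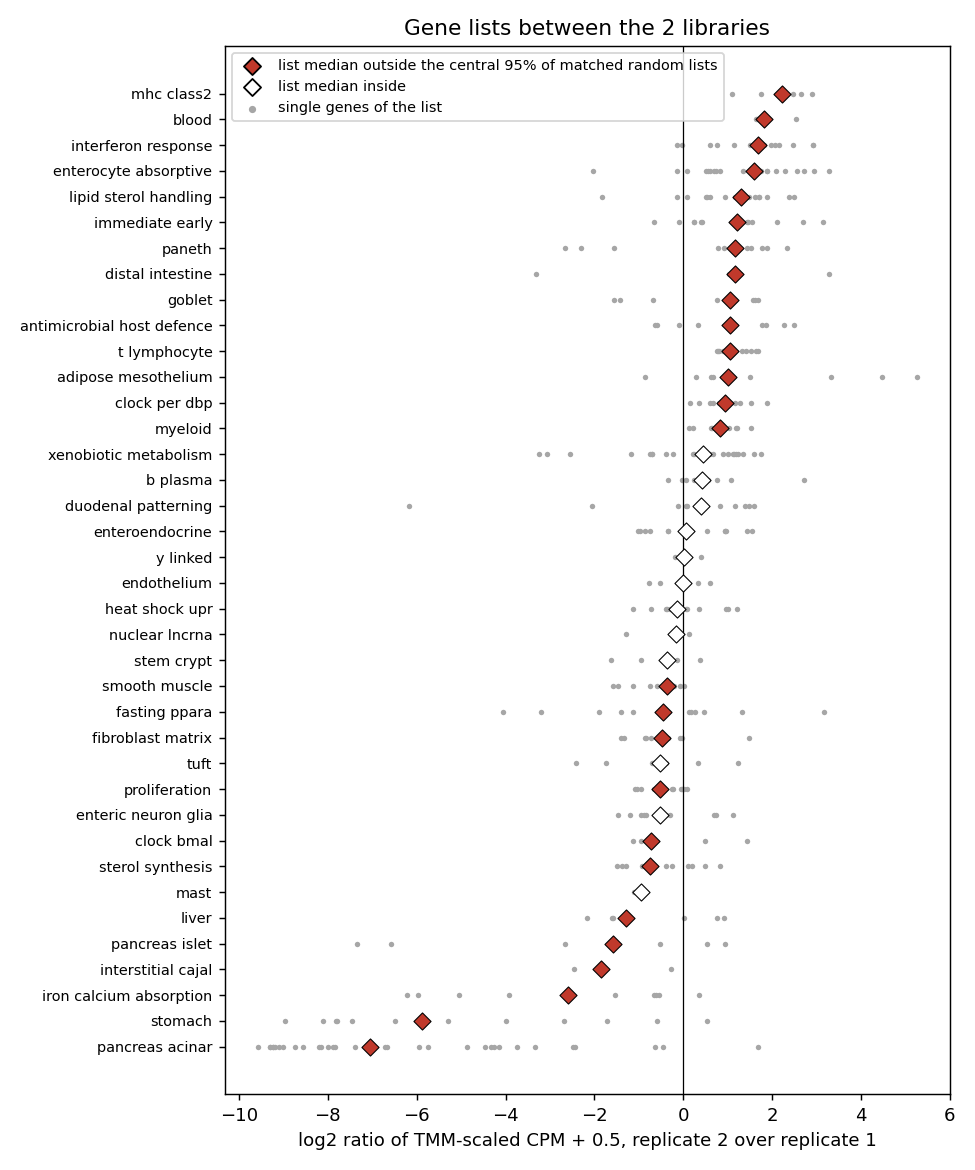
Median log2 ratio of each gene list (diamonds, x axis, replicate 2 over replicate 1, TMM-scaled CPM plus 0.5) with its single genes as grey points, and the list names on the y axis. Filled diamonds are the 26 lists outside the central 95% of matched random lists, from −7.05 for the exocrine pancreas to 2.22 for class II antigen presentation.

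Genes were ranked by the ratio of CPM plus 0.5, which places genes of few counts lower than their count folds do. The 12 largest ratios towards replicate 2 included several transporters. Enpp7, an intestinal sphingomyelinase (ENSMUSG00000046697.12, chromosome 11, 118988188 to 118993221), lay at 2.53 and 746 TPM, 323-fold higher in replicate 2 (95% interval 271 to 388). The phosphate transporter Slc34a2 was 224-fold higher (95% interval 174 to 293), Fam151a 154-fold, Eno1b (a copy of Eno1, so its reads are uncertain) 151-fold, the transcription factor Osr2 142-fold, Clca4a 115-fold and the vitamin C transporter Slc23a1 73.5-fold. The sodium-coupled transporters Slc5a12 and Slc5a8 had 0 and 2 counts in replicate 1. Slc5a12 was at least 291-fold higher in replicate 2, and Slc5a8 had a ratio of 428 with an interval of 118 to 3542. The immunoglobulin segment Ighv1-34 and Cfd completed the named genes of that direction, with 1 gene that has no symbol. Towards replicate 1, the 12 largest ratios were all in the acinar, stomach and Brunner's gland lists, from Cpa1 (1018-fold) and Pnlip (885-fold) through Cela3b, Try4, Try5, Cel, Prss2 and Cela2a to Tff2 (415-fold). By count folds some genes in none of these lists lay above Tff2, such as Ins1, S100g, Ins2 (492-fold) and Trpv6. Of 154 genes over 8-fold higher in replicate 1, 38 belonged to these lists, and 65 genes were over 8-fold higher in replicate 2.

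Over all genes, 2899 of 15921 (18.2%) differed by the binomial test and 2-fold, 1490 of them higher in replicate 1 and 1409 higher in replicate 2. Replicate 1 thus held 51.4% of the calls, and with ERCC scaling, added after seeing the data, it held 69.4% (2171 against 956). The median log2 ratio of all genes was −0.04 under TMM, −0.24 under ERCC scaling and −0.15 on the TPM scale, and ratios given here are relative to TMM. The chi-square of homogeneity was 12466300 on 15920 degrees of freedom, 783 per degree of freedom, far more than sampling noise would give for repeated counts of 1 library, which says nothing on whether the tissue came from separate animals. Across 13084 genes, which are not independent replicates, Pearson's r was 0.904 and Spearman's rho 0.898. The biological coefficient of variation was 0.529, and the median of DESeq2's fitted dispersions gave 0.303.

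Y-linked genes were detected at low levels, and Xist was near the floor. The 4 Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y had 406 counts together in replicate 1 and 333 in replicate 2. None was called, and the list median was 0.01 (73.7). Xist, the RNA of the inactive X chromosome of female cells, had 6 counts in replicate 1 and 1 in replicate 2, although the labels give pooled males and females. The Y-linked sum was 3.09 ± 0.382 TPM.

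Isoform shares were compared for the list genes. Of 185 genes examined, 69 had at least 2 transcripts above 1 TPM, and the main transcript held a median of 76.9% of the gene's TPM. Among the 59 genes above 5 TPM in both libraries, the share differed by a median of 5.03 percentage points, and 29 genes had a main transcript above 80% in both. The share differed by over 20 points in 11 genes. The largest gap was in Mogat2, whose main transcript made up 97.3% of TPM in replicate 1 and 46.0% in replicate 2. For Malat1 the main transcript lay at 37.6% and 81.2%, and for Pigr at 68.7% and 100%. In expected counts the main transcripts of these 3 held more, with means of 95.1% for Mogat2, 94.1% for Malat1 and 96.8% for Pigr over both libraries. Shares are estimates of the authors' quantifier and were not tested.

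The series list of splice junctions held 347142 entries with 32399438 reads, in mm9. An entry marked A = 1 had an intron length found in the annotation in 99.8% of cases, against 28.9% for A = 0. Entries with A = 1 made up 34.8% of the list and 91.4% of its reads. Reads from both R1 and R2 supported 31.4% of the entries, and 149138 entries (43.0%) rested on 1 read. The list of contigs held 374846 transcribed stretches over 102 Mb, with a median length of 192 bases.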

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

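The tests of scaling, of another organ's library and of dilution were chosen after the results were seen, and the tests of further pancreatic, gastric and distal genes and of GC content and length were set before theirs, although 2 of the distal genes had already appeared among the largest ratios.

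Reads of the phage phiX, a control added to sequencing runs, were counted in a row that no comparison uses. It held 96924 counts in replicate 1 and 112022 in replicate 2, or 0.215% and 0.247% of the expected counts, above the 3 counts that a count of 0 allows.

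Genes of the exocrine pancreas, stomach and Brunner's gland lists held 13.0% of TPM in replicate 1. In replicate 2 they held 0.630%, or 0.179% without Zg16, which goblet cells express. Highest in replicate 1 were Ctrb1 (31455 TPM), Cela2a (13097 TPM) and Clps (11586 TPM), all of the exocrine pancreas list. A scaling factor moves all genes alike, and the acinar median lay 7.01 below that of all tested genes (a log2 difference of −7.01, 95% interval over resampled members −8.11 to −4.83), which argues against scaling. A library of another organ would have little Cdx1 and Cdx2. Their counts together had a log2 ratio of 1.55 (95% interval of counting error only, 1.52 to 1.57), below the 3 set for that case. The Brunner's gland genes in these shares had no test of their own. RNA of pancreas and stomach attached to the duodenum may account for the pancreatic and gastric genes. Further genes of both, in no earlier list, had medians of −3.06 (−5.17 to 0.95) and −4.62 (−6.43 to −3.17), but the acinar interval reached past the bound of −1, with Spink1 going the other way (46.6 and 242 TPM), so this stays open, and the design, with 1 group, names no biological difference to test.

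Of 11 iron and calcium genes 7 were higher in replicate 1, while of 24 enterocyte genes 15 were higher in replicate 2 and 1 in replicate 1. Dilution by pancreatic and gastric RNA would lower every enterocyte gene of replicate 1, and on the TPM scale without those genes the medians were −2.70 (−5.00 to −0.91) for the iron and calcium list without ferritins and 1.19 (0.484 to 1.48) for enterocytes. The iron interval lay below the 0 or above set for dilution, although the bound of −1 first set was not cleared. That direction was fixed in advance, because the list was already higher in replicate 1 and leaving those genes out only raises replicate 1. The test therefore adds nothing to the direction already seen, which is opposite to that of dilution. The enterocyte interval, a spread between list members, reaches past its bound of 0.5, so that test was not decided. Leaving out the listed genes moved the enterocyte median on the TPM scale only from 1.38 to 1.19. Dilution by the listed genes is thus a small part of that difference, and dilution by RNA of other genes was not tested. After correction for GC content and length the enterocyte median was 1.59 (0.88 to 1.96, 1.60 before), which argues against these as its whole cause. The iron median was −2.44 (−4.87 to −0.76) and had been −2.62 before, so the correction moved it little. Its interval, again a spread between list members, excludes 0 but reaches past the bound of −1 set beforehand, so that test was not decided. A hypothesis that stays open is that the replicates may hold different stretches of the intestine. For it, 12 further genes of distal enterocytes, Slc34a2 and Fam151a among them, had a median of 2.56 (1.37 to 4.14, 100th percentile). That interval includes the enterocyte median of 1.60. Of the ileal genes Fabp6 and Fgf15 had 0 counts in both libraries and Slc10a2 had 8 and 5. These counts bear on the ileum only and cannot tell apart the stretches before it.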

How the results depend on the processing

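ERCC scaling and the settings without the acinar, gastric and Brunner's gland genes were chosen after seeing the data, and the others were planned. Of 487 alternative values for 92 results, 438 kept their level, or their side of the threshold with any called direction, and 0 reversed a called direction. Lists inside the random range were counted as kept while they stayed inside, even where the sign of their median changed. The enteroendocrine median, for example, was 0.07 and became −0.15 under ERCC scaling. The 438 also include values of single libraries. No paired analysis was possible because there is only 1 group. Leaving out 1 of 2 libraries moves a mean by less than 1 SD by construction, so those values say nothing about how firm a level is, and no test can be run on a single library. Depth limits lists of few counts, such as liver and mast cells. The cause was not tested for any change below, except where another unit rescales values or a stricter or looser limit counts other items by construction.

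Limits of that kind gave 7383 genes at a TPM of at least 5 in both libraries, 3381 and 3109 genes at 1.5-fold, 78540 junctions and 177184 contigs at a score of 0.1 or less, 93835 junctions with at least 10 reads and 187157 contigs above the median signal. Pearson's r was 0.871 with a pseudocount of 0.1 and 0.964 without a filter, where Spearman's rho was 0.943. The coefficient of variation was 0.560 without a filter, 0.480 at a mean count of at least 100 and 0.303 with DESeq2. As shares of expected counts, the top 100 genes held 31.4%, the top 1000 held 64.9% and main isoforms held 82.0%.

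Levels moved by more than 1 SD for foreign-compound genes (5571 FPKM), fatty acid oxidation (327 FPKM), skeletal muscle (39.8 FPKM, 46.7 as posterior mean TPM), neurons and glia (42.1 FPKM, 48.1 as posterior mean, 48.6 TPM without mitochondrial genes and spike-ins), Xist (0.235 as posterior mean) and the Y-linked genes (3.90 as posterior mean, 8.27 CPM). FPKM and CPM are other units than TPM, so those values cannot show a change of level. The sum of enterocyte genes, for example, was also lower in FPKM (23122) than in TPM (26181), but within its larger SD.

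Among list differences, means in place of medians ended the calls of goblet (0.46), Paneth (0.48), cell cycle (−0.46), distal intestine (0.57), liver (−0.70), smooth muscle (−0.59), fibroblast (−0.46) and Bmal-phase clock genes (−0.18), and called mast cells (−0.95). The TPM scale ended cell cycle (−0.56) and Bmal-phase genes (−0.82) and called tuft (−0.71), mast (−1.13) and nuclear RNAs (−0.70). Leaving out the 3 lists as well did the same, at −0.73, −1.01, −0.89, −1.30 and −0.89. Under ERCC scaling, which moves lists and random lists nearly alike, goblet (0.82) lay inside the range and mast (−1.11) outside it. In 20 further draws of random lists, made after seeing this, goblet lay outside in 8 under TMM and 6 under ERCC scaling, and mast in 0 and 16, so the goblet change is one of draws. No filter on low counts ended epithelial defence (0.27) and called mast (−0.83). Medians that kept their side also moved by over 1.5 times, for example on the TPM scale without the 3 lists for Per-phase clock (0.28), myeloid (0.49), T lymphocyte (0.66), smooth muscle (−0.68) and islet genes (−2.74).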

Other observations

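The test of ribosomal protein genes was set before its result, though the levels of a few of them had been seen, and no test of this part was chosen only after the result. The genes named in the next paragraph come from lists written after the main comparison had been seen.

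Further genes of distal enterocytes were higher in replicate 2, with all 12 members positive and 10 over 2-fold. The peptidase Naaladl1 lay at 38.1 and 823 TPM, Prss30 at 20.2 and 198 TPM, Dpep1 at 66.7 and 327 TPM and Mep1a at 5.82 and 34.2 TPM, while the bile acid transporter subunit Slc51b was low in both (2.28 and 2.94 TPM). All 7 further stomach genes with enough counts were over 2-fold higher in replicate 1, among them the water channel Aqp5 (95.3 and 0.09 TPM), the tight junction gene Cldn18 (76.0 and 0.22 TPM) and the transcription factor Nkx6-3 (27.9 and 0.04 TPM). Of 6 further acinar genes with enough counts, 4 were over 2-fold higher in replicate 1. Among these the kallikrein Klk1 lay at 761 and 81.4 TPM, Pdia2 at 30.0 and 0.42 TPM and Aqp12 at 31.1 and 0 TPM. Spink1 was over 2-fold higher in replicate 2 (46.6 and 242 TPM), and Tmed6 was below 2-fold (9.67 and 6.41 TPM).

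Gene levels rose with GC content in both libraries up to about 62% GC. Across protein-coding genes, which are not independent, Spearman's rho of TPM with GC content was 0.495 in replicate 1 and 0.499 in replicate 2, and the median TPM in replicate 1 was 0.20 for transcripts of 42 to 46% GC and 13.4 for those of 58 to 62%, but 8.97 for those above 62%. A candidate explanation is GC bias of the libraries. Ribosomal protein genes, whose products are needed in equal numbers, had a rho of 0.492 in the lower library (95% interval 0.308 to 0.645, 75 genes) and 0.516 in the other. Both values lay above the 0.4 set for that case, although the interval reached below it. The test rests on the assumption that the RNA levels of these genes are equal too, other causes of such a trend were not excluded, and no biological explanation was tested.

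Levels of transcripts of low GC content varied, in examples picked after their values were seen. Fabp1, the fatty acid binding protein of enterocytes, lay at 130.3 and 112 TPM with 45.8% GC, Fabp2 at 27.4 and 84.0 TPM with 42.4% GC, and Malat1 at 42.3 and 21.0 TPM (4925 and 4636 counts) with 42.5% GC. The immunoglobulin J chain gene Jchain lay at 599 and 527 TPM with 39.3% GC, and mt-Co1 at 6261 and 4533 TPM with 39.9% GC. Xist, at 41.4% GC and 17769 bases, had 6 and 1 counts. The ratio between the libraries had a rho of 0.176 with GC content and −0.114 with length.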
